A study of Bos taurus with 18 samples.

How the data were processed

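The series measured RNA of bovine preovulatory follicles on Affymetrix 3' expression arrays. Each of 6 cows gave 1 dominant follicle, 3 before the LH surge and 3 at 22 h after GnRH given to induce it. Membrane-associated granulosa, aspirated antral granulosa and theca of each follicle gave 18 arrays in 6 groups of 3. Per the labels' protocols, RNA was extracted with Trizol and phase lock tubes, and biotin-labelled cRNA was made with a 3' IVT kit. Per the submitters' processing notes, values were made with RMA in Partek 6.5, whose settings are not given. The deposited values are log2 signals per probe set: 24128 entries from 2.29 to 14.9, with array medians from 5.74 to 5.86. No pair of arrays held identical values, and arrays of a group correlated at 0.97 to 0.99. The number of arrays limits the precision of every value.

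The 112 Affymetrix control probe sets were left out, and 24016 were tested. Of these, 13292 carry 1 gene symbol in the platform's annotation, 86 several and 10638 none. That annotation can be old. Of the probe sets with 1 symbol, 13263 have a gene ID in the RefSeq table, and no symbol changed through it. They stand for 9155 genes, 199 with a placeholder symbol and 2913 with more than 1 probe set. A gene's value is that of its probe set with the highest mean over all arrays. Some groups with a mean below 4.62 had 1 of 3 arrays above it: POSTN, TGFB2, VNN2, EBD (before LH), CHST8 and ESR2 (after LH) in membrane granulosa, NID2 (before) and GCLC (after) in antral granulosa, and CHST11 (before), FSHR and SLC1A3 (after) in theca. Differences from these levels are as fitted. On membrane granulosa arrays before LH INHBA lay within 0.08 of the brightest value, as did INHA in cow D there, INSL3 in theca of cow B and TNFAIP6 in antral granulosa of cow A after LH. Differences from such levels can be understated.

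All comparisons were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with the Benjamini-Hochberg correction over all tested probe sets and a threshold of 0.05. LH effects compare different cows, with a mean for each of the 6 groups and no block. Contrasts of theca or antral granulosa with membrane granulosa, and the differences in LH effect, are within cows, with the cow as a fixed block. The pairing was checked: after removing group means, arrays of the same cow correlated at -0.02 to 0.69, and 17 of 18 such pairs were over 0.1. Replicate numbers name different cows before and after LH, where the correlation was -0.17 to 0.23. The fits were tested on simulated data, in which changes of 0.5, 1, 2 and 4 (log2) were added to 50 probe sets each. Changes of 2 were found in 84% to 96% and changes of 1 in 30% to 74%, depending on the contrast, with 3 to 9 false calls among 117 to 154. For the difference in LH effect between antral and membrane granulosa 92% and 30% were found.

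The 22 gene lists, 8 of them markers of cell types, were fixed before the data were examined, together with the contrasts, the tests and the rule for named genes. They are steroidogenesis, cholesterol synthesis and uptake, hormone receptors, oestrogen-phase granulosa genes, ovulatory cascade, proteases and inhibitors, extracellular matrix, cell cycle, angiogenesis and hypoxia, inflammation and chemokines, Hedgehog signalling, inhibin, activin and BMP signalling, the IGF system, and immediate early and heat shock genes. The markers are of granulosa, theca, fibroblasts, smooth muscle and pericytes, endothelium, leukocytes, red cells and the oocyte. Of 444 listed genes 352 are measured, and 43 are in more than 1 list. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast, with an estimated correlation and fry as alternatives. Fry asks whether a list's genes move one way on balance, without comparing them with other genes.

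Genes are named by a fixed rule. For each contrast they are the 10 largest rises and 10 largest falls among called genes whose groups do not overlap, or which go the same way in all 3 cows. For contrasts of antral with membrane granulosa and for differences in LH effect they are the 5 largest each way. To these are added up to 4 members per list with the smallest adjusted p, from which examples are given, and 18 genes of follicle function. One of these, MKI67, has no probe set. Alternatives were quantile normalization, centring each array on its median, leaving out the dimmest probe sets, 1 probe set per gene, eBayes with trend and robust, a 2-fold minimum, only the arrays compared, other blocks, and each cow left out in turn. Antral granulosa in place of membrane granulosa was added after seeing the data. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.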

Results

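The series asks whether the LH surge acts differently on the granulosa and the theca of the bovine preovulatory follicle. Each cow gave 1 dominant follicle. Cows D, F and G gave theirs before LH, and cows A, B and C 22 h after GnRH, which sets off the surge. Membrane-associated granulosa, aspirated antral granulosa and theca of each follicle went on separate expression arrays. Replicates are therefore separate cows, and each of the 6 groups holds 3 arrays. The first principal component of the 18 arrays held 41.7% of the variance and the second 31.3%. On the first, the granulosa arrays before LH lay between 60 and 93.9, those after LH between -44.9 and 3.88, and the theca arrays between -81.1 and -32.0. The third component, with 6.30%, set the 3 arrays of cow C apart (27.5 to 52.7). Changes are log2 fold changes ± standard error with n = 3 cows per group. The standard error uses a spread per probe set that all 6 groups share, and so does not give the spread of the cows compared. Adjusted p is that of limma with the Benjamini-Hochberg correction over 24016 probe sets, and each gene is read from its probe set of highest mean. The files hold no detection calls. Where a probe set lay below 4.62, the limit under which the means of the 8005 dimmest probe sets lie, on every array of a group, its difference is given as at least the other group's mean less this limit, with the fit's adjusted p, and no size is given where both groups lay below it. Leaving out a cow removes its 3 arrays, so a contrast within cows at that time then rests on 2 cows.

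**Figure D1:**
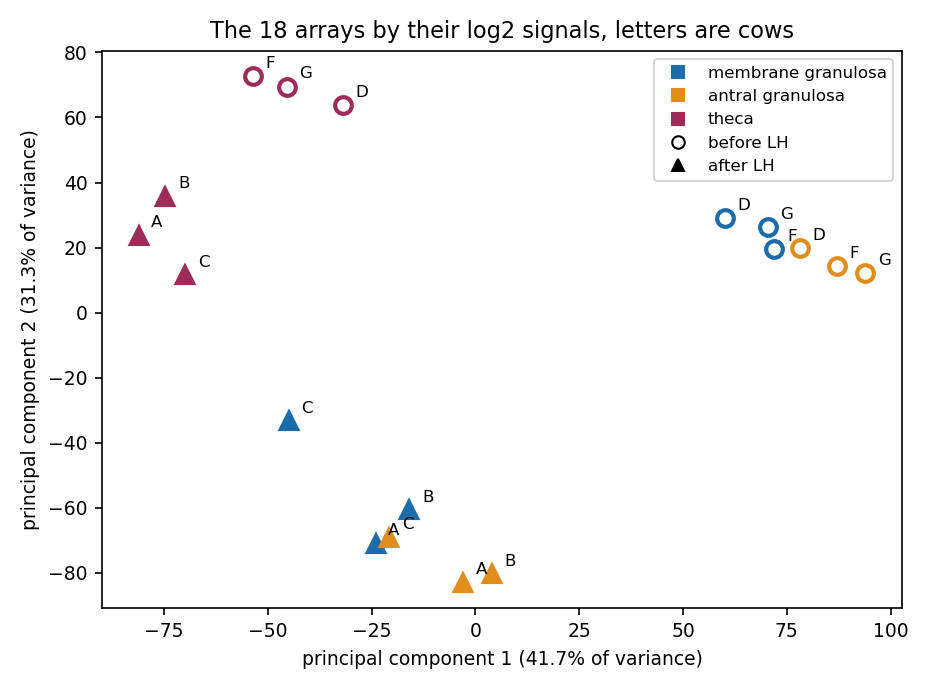
Scores of the 18 arrays on principal components 1 (41.7% of variance) and 2 (31.3%), in units of log2 signal; each point is 1 array, colour gives the cell population, fill gives the time, and letters are cows. Granulosa arrays lie at 60 or above on component 1 before LH and at 3.88 or below after LH.

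In membrane granulosa, PTX3, PTGS2 and VNN2 were among the genes that rose after LH, and CYP19A1 and LHCGR among those that fell. PTX3, whose protein organises the hyaluronan matrix of the cumulus, rose by at least 8.79 (adjusted p = 3.88e-11), from a mean of 3.94 to 13.4. PTGS2, the inducible enzyme of prostaglandin synthesis, rose by at least 7.30 (adjusted p = 1.31e-07), and VNN2, a pantetheinase, by 7.14 ± 0.77 (adjusted p = 7.08e-06). CYP19A1, the aromatase that makes oestradiol, fell by 9.07 ± 0.65 (adjusted p = 1.48e-07). LHCGR, the receptor for LH, fell by 4.10 ± 0.35 (adjusted p = 6.81e-07). In all, 5041 probe sets passed an adjusted p of 0.05, 2413 higher and 2628 lower, for 2385 genes. Rises were the more frequent at 2-fold or more (1363 and 1225) and without cow C (2726 and 2679). The groups of 3 did not overlap for 34.5% of all probe sets, where chance gives 10%.

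Other large rises were those of the matrix protein POSTN (7.61 ± 0.39), the peptide NTS (by at least 6.16), the caveolar protein CAV1 (6.37 ± 0.24) and the decoy receptor TNFRSF6B (6.34 ± 0.24). The glutamate receptor subunit GRIA3 (by at least 4.78), the growth factor TGFB2 (6.14 ± 0.53) and the tight junction protein CLDN11 (5.91 ± 0.49) followed. Large falls were those of the sulfotransferase CHST8 (-6.49 ± 0.31), the nitric oxide synthase NOS2 (-5.59 ± 0.39), GCLC (-5.54 ± 0.34) of glutathione synthesis, the pseudokinase TRIB2 (-5.06 ± 0.68) and the lipoprotein receptor LRP8 (-4.93 ± 0.48). INHBA (-4.88 ± 0.70), a subunit of activin A, the troponin TNNI3 (-4.80 ± 0.25), the cyclin CCND2 (-4.77 ± 0.26) and the aminotransferase GPT (-4.73 ± 0.29) fell as well. The largest adjusted p among these 16 genes was 0.000107. Another probe set of NOS2, above 4.62 on all these arrays, read -1.70 (adjusted p = 0.000129). OXT, the oxytocin precursor, rose by 4.05 ± 1.01, being the brightest probe set on the array of cow C, and ADAMTS1, a protease of the ovulating follicle, by 3.09 ± 0.32. FSHR, the receptor for FSH, fell by 1.97 ± 0.43, and CYP17A1, which makes androgen, was lower on these arrays by 3.38 ± 0.93 (adjusted p = 0.0157). Its levels before LH (10.4, 4.90 and 8.84 in cows D, F and G) had the order of those of the theca hormone INSL3 (14.04, 10.87 and 13.60) and of STAR (11.6, 7.81 and 9.66), so a fall in granulosa is not separated from theca RNA on these arrays. The CYP17A1 call ended without any 1 of cows A, B, C, D or G (adjusted p 0.0539 to 0.106). CYP11A1 (-3.32 ± 1.23, adjusted p = 0.0686), TNFAIP6 (1.72 ± 0.61, adjusted p = 0.0583), STAR (0.23 ± 1.22), HSD3B1 (-1.13 ± 0.88), INHA, INSL3 and PGR were not called. Calls of CYP11A1 (adjusted p = 6.05e-05) and HSD3B1 (0.0270) appeared without cow C, and of TNFAIP6 (0.0173) without cow G. Another bright probe set of TNFAIP6 was called (3.13, adjusted p = 0.00221). PGR lay below 4.62 on all arrays of each group.

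The ovulatory cascade list had 10 of 22 members higher (PTX3, PTGS2, TIMP1) and 2 lower, and 11 and 2 adjusted over the list alone. Camera called it higher (median 1.78, adjusted p = 3.52e-06), with adjusted p = 0.0210 with an estimated correlation. The calls of this list after LH in the 3 populations are the only list calls of any contrast that hold with an estimated correlation. Of 33 cell cycle genes 29 fell and none rose (31 adjusted over the list alone), with the kinetochore gene NDC80 (-3.52 ± 0.26), survivin or BIRC5 (-3.35 ± 0.22) and the cyclin CCNB2 (-3.23 ± 0.25) among them. Camera called this list lower (median -2.15, adjusted p = 1.47e-22), with adjusted p = 0.117 with an estimated correlation. Oestrogen-phase granulosa genes had 10 of 19 lower and 3 higher (12 and 3 adjusted over the list alone), PTX3 being one of the rises. Granulosa markers had 7 of 13 lower and 2 higher (9 and 2 adjusted over the list alone), with HSD17B1 (-4.05 ± 0.35), which makes oestradiol from oestrone, and the gap junction gene GJA1 (-1.32 ± 0.15). Hormone receptors had 6 of 14 lower (7 adjusted over the list alone), with LHCGR, FSHR and the oestrogen receptor ESR2 (-1.22 ± 0.21). Camera called these 3 lists lower (adjusted p = 0.00142, 0.00142 and 0.00800). In turn, these had adjusted p = 0.172, 0.175 and 0.0826 with an estimated correlation.

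Immediate early and heat shock genes had 11 of 21 higher after LH in membrane granulosa, with the transcription factors FOS (5.33 ± 0.44) and EGR1 (3.37 ± 0.45), whose other probe set read 0.24 (adjusted p = 0.328) (12 higher and 2 lower adjusted over the list alone). Inflammation genes had 5 of 28 higher (5 adjusted over the list alone), led by the cytokine IL18 (5.30 ± 0.62). Extracellular matrix genes had 9 of 29 higher and 3 lower (9 and 3 adjusted over the list alone), with THBS2 (3.32 ± 0.31) beside POSTN. Proteases and inhibitors had 10 of 29 higher and 3 lower (12 and 5 adjusted over the list alone), with the inhibitor TIMP1 (5.26 ± 0.42) and the plasminogen activator PLAT (1.83 ± 0.27). Camera called these 4 lists higher (adjusted p = 0.000999, 0.00800, 0.0188 and 0.0177). The lists had adjusted p = 0.172, 0.345, 0.587 and 0.415 with an estimated correlation. Their members lay higher in cow C than in cows A and B, by medians of 0.31, 0.65, 0.82 and 0.36. Cholesterol synthesis and uptake had 4 of 20 lower and 1 higher (5 and 1 adjusted over the list alone), with a median of -0.74 and camera adjusted p = 0.0638. Without cow C, whose members of this list lay a median of 1.45 above those of cows A and B, 13 were lower, and without cow A or G 2. Steroidogenesis had 4 of 16 lower and 1 higher, the cholesterol-binding TSPO (3.05 ± 0.26). The IGF system (1 higher and 4 lower of 13), inhibin, activin and BMP signalling (3 and 5 of 22), angiogenesis and hypoxia (5 and 2 of 25) and Hedgehog signalling (0 and 1 of 5) were not called as lists. Without cow A or G the angiogenesis list had 3 higher, and without cow C 5 lower. Nor were markers of fibroblasts (2 and 1 of 15), theca (2 and 2 of 11), smooth muscle (0 and 2 of 11), endothelium (2 and 0 of 17), leukocytes (1 and 1 of 22), red cells (0 and 1 of 8) and the oocyte (0 and 0 of 9). For leukocyte markers the median was positive and the camera direction negative.

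In antral granulosa too, PTX3 and PTGS2 rose after LH and CYP19A1 fell. PTX3 rose by at least 8.55 (adjusted p = 2.10e-11), CAV1, which shapes caveolae, by at least 8.05 (adjusted p = 5.54e-12), and PTGS2 by at least 7.44 (adjusted p = 1.05e-07). CYP19A1 fell by at least 8.10 (adjusted p = 1.64e-07). CCND2, a cyclin of the G1 phase, fell by 6.36 ± 0.26 (adjusted p = 4.02e-10). Here 5391 probe sets were called, 2473 higher and 2918 lower, for 2625 genes. The groups did not overlap for 36.7% of probe sets, where chance gives 10%. Further rises were those of POSTN (by at least 6.98), CLDN11 (by at least 7.16), the basement membrane protein NID2 (7.27 ± 0.64), the secreted DKK3 (by at least 6.53), the small GTPase RND3 (7.15 ± 0.27), VNN2 (6.86 ± 0.77) and NTS (by at least 6.26). Another probe set of CLDN11, above 4.62 on all arrays, rose by 2.16. Further falls were those of CHST8 (by at least 6.55), NOS2 (-6.12 ± 0.39), GCLC (-5.90 ± 0.34), HSD17B1 (-5.66 ± 0.35), TNNI3 (-5.36 ± 0.25), the replication factor PCLAF (-5.30 ± 0.49), PLEK (by at least 4.48) and PRR15 (-4.97 ± 0.30). The largest adjusted p among these 15 genes was 8.00e-06. Another probe set of NOS2, above 4.62 on all antral arrays, read -1.56 (adjusted p = 0.000243).

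ADAMTS1 (4.83 ± 0.32), the hyaluronan-binding TNFAIP6 (by 3.10 or more; 4.31 by its other probe set) and OXT (3.99 ± 1.01, adjusted p = 0.00892) rose in antral granulosa, and INHBA (-4.88 ± 0.70), LHCGR (-2.98 ± 0.35) and FSHR (-2.02 ± 0.43) fell. The other probe set of ADAMTS1 rose by 0.99 (adjusted p = 0.0491), with 1 of 3 arrays before LH above 4.62. After LH TNFAIP6 lay at 14.5 to 14.6 on all antral arrays, close to the brightest value of 14.6 in cow A, so its rise can be understated. CYP11A1, the first enzyme of steroid synthesis, fell by 3.90 ± 1.23 (adjusted p = 0.0314). Its level on the cow C array was 11.8 after LH, against 9.16 in cow A and 6.38 in cow B. The CYP11A1 call ended without any 1 of cows A, B, D, F or G (adjusted p 0.0833 to 0.137), and the OXT call without cow G (adjusted p = 0.0566). STAR, which carries cholesterol into mitochondria, was not called (2.34 ± 1.22, adjusted p = 0.206) but was without cow B (adjusted p = 0.0395). HSD3B1, CYP17A1, INHA, INSL3 and PGR were not called.

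The ovulatory cascade had 12 of 22 higher and 1 lower in antral granulosa (12 and 2 adjusted over the list alone). Its median was 2.54 (camera adjusted p = 2.13e-06, and adjusted p = 0.0182 with an estimated correlation). Of 33 cell cycle genes 31 fell (31 adjusted over the list alone), with BIRC5 (-4.22 ± 0.22) and UBE2C (-3.85 ± 0.25). Their median was -3.03 (camera adjusted p = 9.86e-24, and adjusted p = 0.121 with an estimated correlation). Extracellular matrix genes had 12 of 29 higher and 4 lower (14 and 4 adjusted over the list alone), THBS2 (4.29 ± 0.31) among the rises. Fibroblast markers had 6 of 15 higher and 1 lower (6 and 1 adjusted over the list alone), with the collagens COL3A1 (by at least 2.72) and COL1A2 (2.67 ± 0.64). Proteases and inhibitors had 10 of 29 higher and 3 lower (12 and 4 adjusted over the list alone), with TIMP1 (6.41 ± 0.42) and PLAT (3.22 ± 0.27). Immediate early and heat shock genes had 11 of 21 higher and 2 lower (12 and 2 adjusted over the list alone), with FOS (5.33 ± 0.44) and EGR1 (2.99 ± 0.45). The other probe set of EGR1 read 0.49 (adjusted p = 0.0309). Inflammation genes had 5 of 28 higher (5 adjusted over the list alone). Camera called these 5 lists higher (adjusted p = 0.000129, 0.00731, 0.00731, 0.00115 and 0.0247). They had adjusted p = 0.373, 0.374, 0.367, 0.198 and 0.386 with an estimated correlation. Without cow D the fibroblast and inflammation counts were 3 each, and without cow A the fibroblast count was 3. On the antral array of cow C fibroblast markers lay a median of 0.82 above those of cows A and B, with 12 of 15 above 0.

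Oestrogen-phase genes had 11 of 19 lower and 3 higher in antral granulosa (12 and 3 adjusted over the list alone), granulosa markers 7 of 13 lower and 2 higher (8 and 2 adjusted over the list alone), and hormone receptors 7 of 14 lower (7 adjusted over the list alone). Camera called the 3 lists lower (adjusted p = 0.00260, 0.00486 and 0.0215). None of the 3 held with an estimated correlation (adjusted p = 0.198, 0.273 and 0.121). Without cow A 4 hormone receptors were lower. Cholesterol genes had 4 of 20 lower and 1 higher, with a median of -0.88 and camera adjusted p = 0.0804. Of them 12 were lower without cow C, and 2 without cow A, B, D or G. Steroidogenesis had 2 of 16 higher and 4 lower, 2 lower without cow B, D or F. Its median was 0.02, with a sign that turns with the scaling of the arrays, and its mean -0.76. The IGF system (3 and 3 of 13), BMP signalling (3 and 5 of 22), angiogenesis and hypoxia (3 and 5 of 25) and Hedgehog signalling (0 and 1 of 5) were not called as lists. Without cow D the angiogenesis list had 3 lower, and without cow C the angiogenesis and BMP lists had 5 higher each. Markers of theca (1 and 2 of 11), smooth muscle (2 and 2 of 11), endothelium (1 and 0 of 17), leukocytes (0 and 1 of 22), red cells and the oocyte (0 and 0) were not called either.

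**Figure D2:**
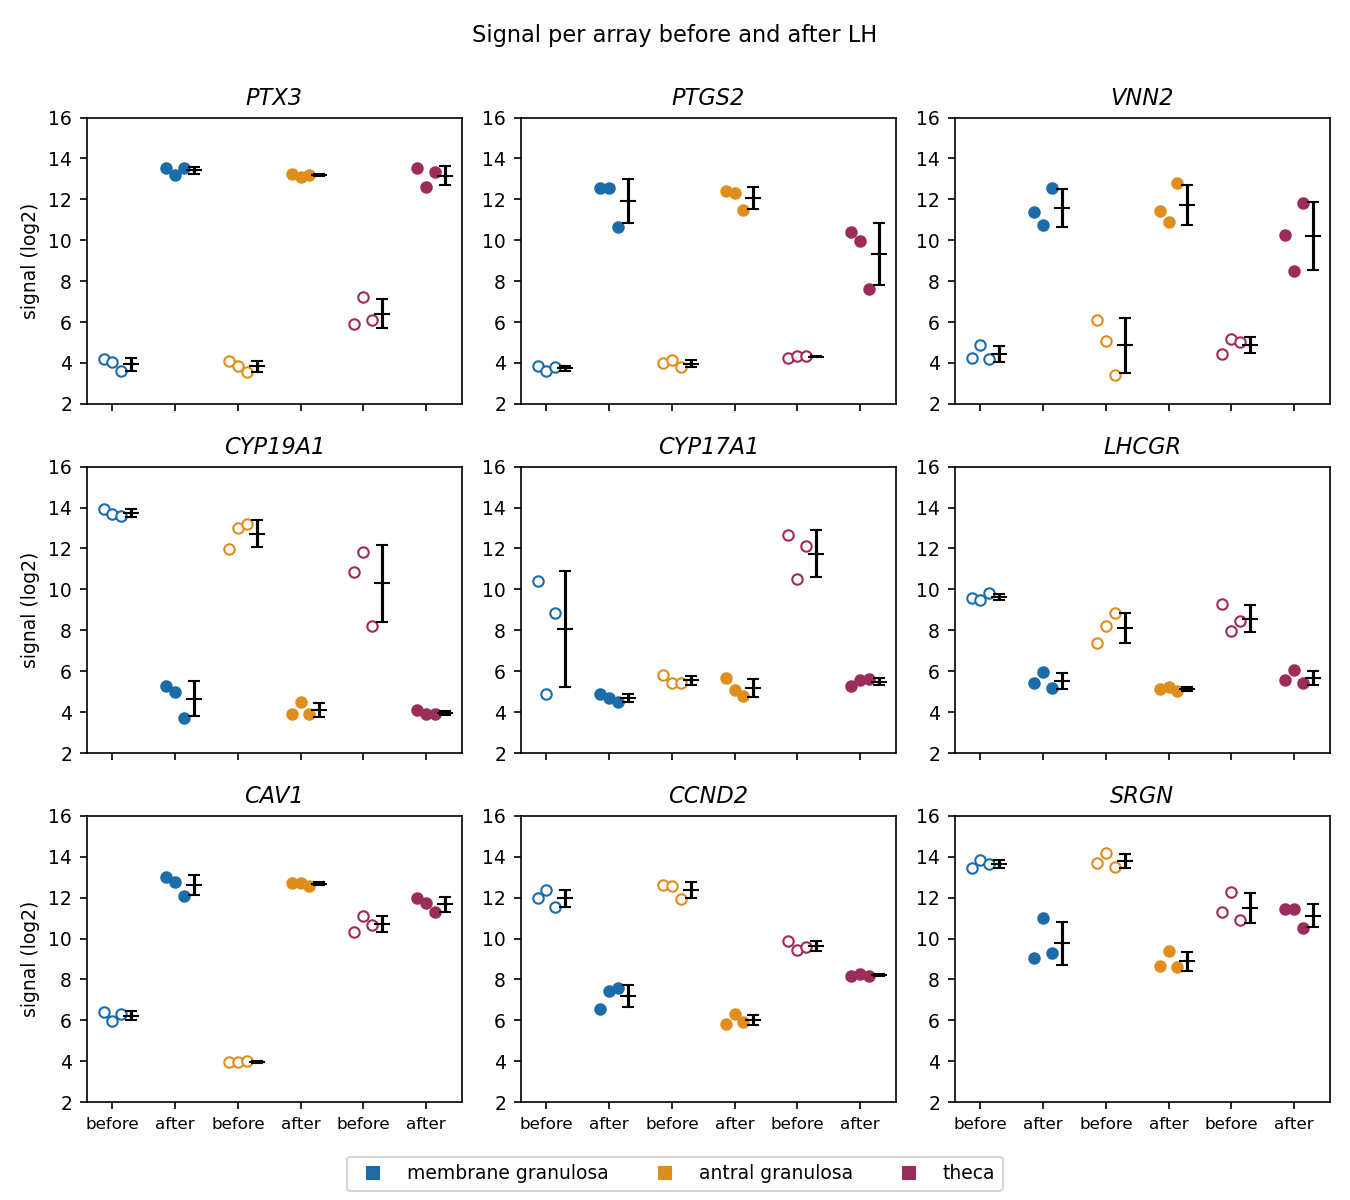
Log2 signal of 9 genes on each array, by cell population (colour) and time (open before, filled after LH); points are cows, and bars give the mean and standard deviation of 3 cows. PTX3 reaches means of 13.2 to 13.4 after LH in the 3 populations, and the LH effect on SRGN, CCND2 and CAV1 differs between theca and membrane granulosa by 3.50, 3.34 and -5.40.

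In theca, PTX3, VNN2 and PTGS2 rose after LH, and CYP17A1, an enzyme of androgen synthesis, and LHCGR fell. CYP17A1 fell by 6.27 ± 0.93 (adjusted p = 0.000950), from a mean of 11.8 to 5.48. PTX3 rose by 6.76 ± 0.29 (adjusted p = 7.78e-09), VNN2 by 5.31 ± 0.77 (adjusted p = 0.000847) and PTGS2 by at least 4.70 (adjusted p = 0.000135). LHCGR fell by 2.88 ± 0.35 (adjusted p = 0.000185). INSL3, a peptide hormone of theca, was not called (adjusted p = 0.806). It was the brightest probe set on the theca arrays of cows F and G before LH, where a ceiling would hide a change. The calls numbered 941, 431 higher and 510 lower, for 475 genes. The groups did not overlap for 20.4% of probe sets, where chance gives 10%. The count of 941 was 439 without cow A, 465 without cow D and 571 without cow G, and 514 with only the theca arrays fitted. Rises were then the more frequent (278 and 236), as at 2-fold or more (307 and 262) and without cow C (544 and 472).

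Other large rises in theca were those of the protease inhibitor SERPINA14 (4.54 ± 0.83), the metallothionein MT2A (4.50 ± 0.55), the tight junction protein CLDN1 (4.29 ± 0.71), the collagen crosslinker LOXL4 (4.23 ± 0.47), the phosphohydrolase NUDT11 (3.80 ± 0.49) and POSTN (3.74 ± 0.39). Large falls were those of CYP19A1 (by at least 5.67), INHBA (-5.48 ± 0.70), the scaffold protein ANKS4B (by at least 3.24), CHST8 (by at least 3.46), the troponins TNNT1 (-3.95 ± 0.32) and TNNI3 (-3.39 ± 0.25), the transporters SLC35G1 (-3.43 ± 0.40) and SLC1A3 (-3.40 ± 0.35), and TRIB2 (-3.37 ± 0.68). The largest adjusted p among these 15 genes was 0.00991. Another probe set of CYP19A1 was not called (-1.60, adjusted p = 0.0748; 1 of 3 arrays above 4.62 after LH). CYP19A1, a granulosa transcript, stood at a mean of 10.3 on the theca arrays before LH. OXT rose by 3.93 ± 1.01 (adjusted p = 0.0409), and stood at 14.4 in cow C against 9.89 and 9.33 in cows A and B. TNFAIP6 rose by 3.27 ± 0.61 (adjusted p = 0.00558). Calls ended without 1 cow for SERPINA14 (D or G, adjusted p 0.0581 to 0.0640), TRIB2 (A, D, F or G, adjusted p 0.0663 to 0.0715), OXT (A, D, F or G, adjusted p 0.0832 to 0.167) and TNFAIP6 (A, adjusted p = 0.0623). ADAMTS1 was not called (1.17 ± 0.32, adjusted p = 0.0568) but was without cow B (adjusted p = 0.0334), and its other probe set was called with all cows (1.55, adjusted p = 0.0173). STAR (-1.10 ± 1.22), CYP11A1 (-1.33 ± 1.23), HSD3B1, INHA, FSHR and PGR were not called.

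The ovulatory cascade had 9 of 22 higher and 1 lower in theca (11 and 1 adjusted over the list alone). Its median was 1.58 (camera adjusted p = 1.30e-08, and adjusted p = 0.00437 with an estimated correlation). Cholesterol synthesis and uptake had 6 of 20 lower and none higher (9 adjusted over the list alone). Among them were the sterol reductase TM7SF2 (-2.24 ± 0.35) and mevalonate kinase, MVK (-0.99 ± 0.13). The other probe sets of MVK read -1.50 (adjusted p = 0.00298) and -0.45 (adjusted p = 0.0518). The median of the list was -1.17 (camera adjusted p = 4.82e-08, and adjusted p = 0.230 with an estimated correlation). In cow C the theca values of this list lay a median of 1.42 above those of cows A and B, and 17 members were lower without cow C and 2 without any other cow. Steroidogenesis had 4 of 16 lower and TSPO higher (4 and 1 adjusted over the list alone). Among the falls were HSD17B1 (-2.51 ± 0.35) and the nuclear receptor NR5A1 (-1.48 ± 0.19). The other probe sets of NR5A1 read -1.12, -0.41 and -0.12 (adjusted p = 0.0131, 0.137 and 0.745). Oestrogen-phase genes had 6 of 19 lower and 2 higher (9 and 2 adjusted over the list alone), and granulosa markers 3 of 13 lower and 1 higher (6 and 1 adjusted over the list alone). Camera called these 3 lists lower (adjusted p = 0.0162, 0.00231 and 0.00410). The lists had adjusted p = 0.177, 0.212 and 0.230 with an estimated correlation. No cell cycle gene of 33 was called in theca by limma, over all tests or adjusted over the list alone, and 5 had an unadjusted p under 0.05. Without cow B 4 were lower. Camera called the cell cycle list lower (median -0.35, adjusted p = 0.000342), with adjusted p = 0.541 with an estimated correlation, and fry gave adjusted p = 0.187.

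Inflammation genes had 5 of 28 higher after LH in theca (7 adjusted over the list alone), with IL18 (2.91 ± 0.62, adjusted p = 0.0136; 0.0919 without cow A and 0.0992 without cow G). The count was 1 without cow A or G, 2 without cow D, 3 without cow B and 9 without cow C. Immediate early and heat shock genes had 4 of 21 higher (8 adjusted over the list alone), with FOS (2.84 ± 0.44) and JUNB (2.09 ± 0.37), and 2 without cow D and 8 without cow B. Proteases and inhibitors had 4 of 29 higher (5 adjusted over the list alone), with the urokinase receptor PLAUR (3.55 ± 0.66), TIMP1 (3.37 ± 0.42) and PLAT (2.06 ± 0.27). Extracellular matrix genes had 3 of 29 higher (3 adjusted over the list alone), with THBS2 (2.42 ± 0.31). Angiogenesis and hypoxia genes had 2 of 25 higher and 1 lower (4 and 1 adjusted over the list alone), and fibroblast markers 1 and 1 of 15 (2 and 1 adjusted over the list alone). Camera called these 6 lists higher (adjusted p = 2.02e-05, 0.000342, 0.000986, 0.0152, 0.0482 and 0.0429). They had adjusted p = 0.177, 0.177, 0.230, 0.555, 0.292 and 0.538 with an estimated correlation. Hormone receptors (0 and 2 of 14), the IGF system (0 and 1 of 13), BMP signalling (0 and 2 of 22) and Hedgehog signalling (0 and 0 of 5) were not called as lists. Markers of theca (0 and 1 of 11), smooth muscle (0 and 1 of 11), endothelium (1 and 0 of 17), leukocytes (1 and 0 of 22), red cells (0 and 0 of 8) and the oocyte (0 and 1 of 9) were not called either.

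**Figure D3:**
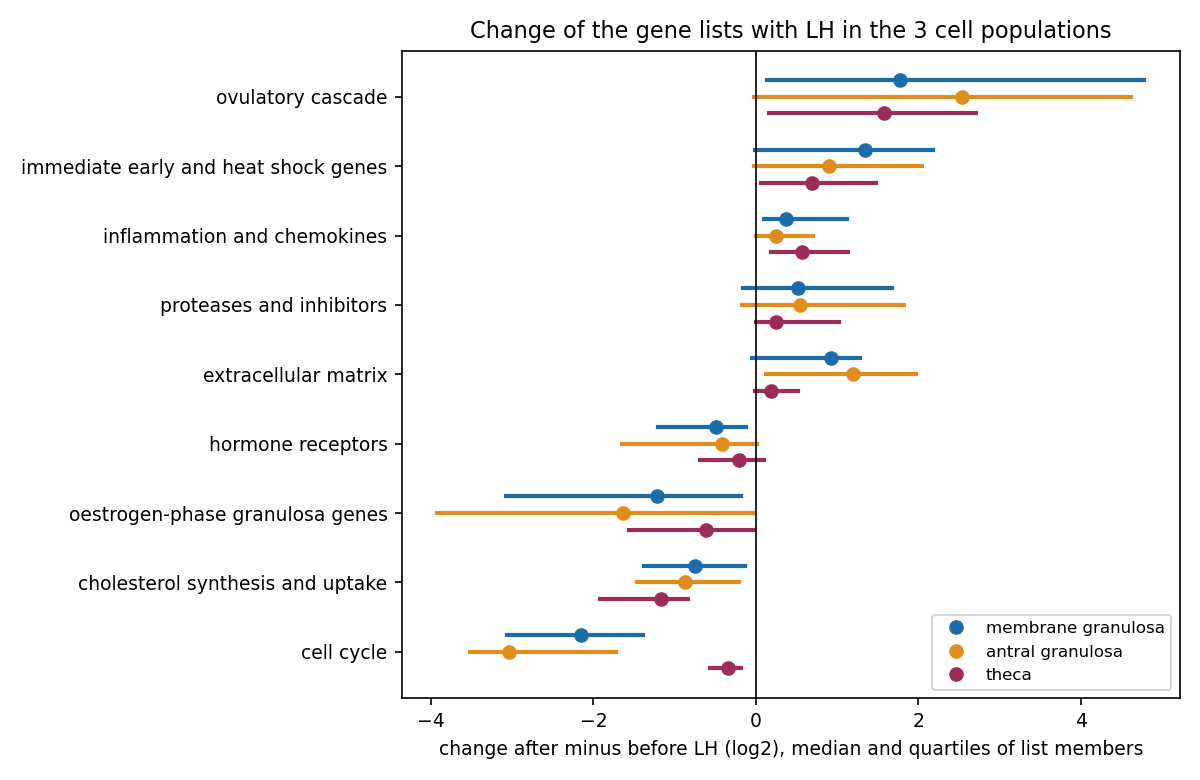
Change after minus before LH (log2, horizontal axis) of 9 gene lists in the 3 cell populations (colours); dots are medians over the measured list members and lines run from the lower to the upper quartile. The cell cycle median is -2.15 in membrane granulosa, -3.03 in antral granulosa and -0.35 in theca.

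The LH responses of the 3 populations overlapped in more probe sets than independent responses would share. Membrane and antral granulosa shared 1787 rises and 1915 falls (248 and 319 by chance), with no probe set called in opposite directions. Theca shared 325 rises and 329 falls with membrane granulosa (43.3 and 55.8 by chance), with 6 called in opposite directions. With antral granulosa it shared 305 and 317 (44.4 and 62.0 by chance), with 17 called in opposite directions. Rises in all 3 populations numbered 293, PTX3, PTGS2 and VNN2 among them, and falls 291, CYP19A1, LHCGR and INHBA among them, of 6962 probe sets called in at least 1. Across probe sets, which are not independent replicates, the changes correlated at 0.91, 0.67 and 0.61 for these 3 pairs. The same 6 cows gave all 3 populations, and other groupings of the cows gave 0.62 to 0.76, 0.33 to 0.59 and 0.24 to 0.53. Each of these groupings still sets unequal numbers of cows after LH against each other. They therefore keep part of the LH response and do not measure what shared cows alone give. The overlaps of theca with membrane and antral granulosa, 654 and 622 probe sets, were 309 and 293 without cow A, 289 and 282 without cow D, 395 and 390 without cow G, and 439 and 410 without cow F. RNA of one population on the arrays of another could add to these overlaps. Of the 510 falls in theca, 142, CYP19A1 among them, were called higher on membrane granulosa than on theca arrays before LH.

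The LH effect in theca differed from that in membrane granulosa for genes such as CCND2, which fell in granulosa, and CAV1, which rose more in granulosa. CCND2 fell by 4.77 ± 0.26 in membrane granulosa, and its LH effect in theca lay 3.34 ± 0.30 above that (adjusted p = 8.02e-05). CAV1 rose by 6.37 ± 0.24 in membrane granulosa, and its LH effect in theca differed by -5.40 ± 0.28 (adjusted p = 3.58e-06). PTX3 rose less in theca, by at least 2.04 (adjusted p = 0.000492). Its mean before LH was 6.41 in theca and 3.94, below the limit, in membrane granulosa, and its means after LH were 13.2 and 13.4, so the difference comes from the levels before LH. PTGS2 was called too (adjusted p = 0.000331), but lay below the limit before LH in both populations, so no size is given. SLC7A5, an amino acid transporter, went from 5.76 to 8.71 in theca and from 7.10 to 6.65 in membrane granulosa (difference 3.40 ± 0.33, adjusted p = 0.000114). The difference was called for 2192 probe sets, 1095 positive and 1097 negative, and the within-cow differences of the 2 times did not overlap for 26.9% of probe sets (10% by chance). The count was 1074 without cow A, 1190 without cow B and 1301 without cow G.

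Of the 2192 probe sets, 1621 were called in membrane granulosa and not in theca, and 110 in theca and not in membrane granulosa. In both, 228 were called in the same direction and 6 in opposite directions, and 227 in neither. The change in theca had the same sign and was smaller for 1443, larger for 89, and of opposite sign for 660. The other largest positive differences were those of the proteoglycan SRGN (3.50 ± 0.42), the exchange factor RASGEF1B (3.41 ± 0.52) and the Notch ligand DLL4 (3.34 ± 0.25). SRGN went from 13.6 to 9.77 in membrane granulosa and from 11.5 to 11.1 in theca. The largest negative differences after CAV1 were those of CLDN11 (-5.17 ± 0.57), the junction protein LMO7 (-4.96 ± 0.35), TGFB2 (-4.96 ± 0.43) and the collagen hydroxylase P4HA3 (-4.53 ± 0.35). Another probe set of CLDN11, above the limit on all these arrays, read -2.28 (adjusted p = 0.0227). One of LMO7, below the limit on all theca arrays, was not called (-1.13, adjusted p = 0.154). ADAMTS1 differed by -1.93 ± 0.31 (adjusted p = 0.00232; its other probe set -0.64, adjusted p = 0.372). CYP17A1 (-2.89 ± 0.93, adjusted p = 0.0766), CYP19A1 (adjusted p = 0.0703), FSHR (1.35 ± 0.39, adjusted p = 0.0525), LHCGR (1.22 ± 0.46), VNN2 (-1.83 ± 0.66), CYP11A1 (2.00 ± 0.71), TNFAIP6 (1.55 ± 0.60), INHBA (-0.60 ± 0.46), OXT (-0.12 ± 0.58), STAR, HSD3B1, INHA, INSL3 and PGR were not called. Another probe set of CYP19A1 was (2.62, adjusted p = 0.00841), with 1 of 3 theca arrays after LH above the limit. Calls appeared without cow D for LHCGR (adjusted p = 0.00179), CYP17A1 (0.0269), TNFAIP6 (0.0273), VNN2 (0.0437) and FSHR (0.0439). Others appeared without cow F for CYP17A1 (adjusted p = 0.0170) and CYP19A1 (0.0402), and without cow C for CYP11A1 (0.0147), INHBA (0.0397) and OXT (0.0486).

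Cell cycle genes had 29 of 33 positive differences (30 adjusted over the list alone), with BIRC5 (2.92 ± 0.27), BUB1 (2.90 ± 0.28) and UBE2C (2.72 ± 0.27). Their median was 1.87 (camera adjusted p = 9.62e-26, and adjusted p = 0.343 with an estimated correlation). Granulosa markers had 2 of 13 positive (5 adjusted over the list alone) and were called as a list (adjusted p = 0.0276, and adjusted p = 0.572 with an estimated correlation). The ovulatory cascade had 8 of 22 negative and 1 positive (10 and 2 adjusted over the list alone), with the prostaglandin E synthase PTGES (-3.37 ± 0.44) beside ADAMTS1. Immediate early and heat shock genes had 5 of 21 negative and 1 positive (7 and 2 adjusted over the list alone), with the phosphatase DUSP1 (-1.41 ± 0.28), and 2 negative without cow A and 3 without cow D or G. Cholesterol genes had 2 of 20 negative and 1 positive (2 and 1 adjusted over the list alone), with TM7SF2 (-2.38 ± 0.29), and 4 negative without cow C or F. Camera called these 3 lists more negative in theca (medians -0.21, -0.48 and -0.59, adjusted p = 0.0260, 0.0276 and 0.0260). In turn, these had adjusted p = 0.343, 0.497 and 0.771 with an estimated correlation. Hormone receptors (4 positive and 0 negative of 14; 0 without cow A or G), oestrogen-phase genes (4 and 2 of 19), steroidogenesis (1 and 2 of 16), proteases (1 and 4 of 29), extracellular matrix (3 and 2 of 29) and angiogenesis (2 and 2 of 25) were not called as lists. Inflammation (0 and 3 of 28), the IGF system (4 and 1 of 13), BMP and Hedgehog signalling and the 7 other marker lists were not called either. Without cow A the oestrogen-phase list had 2 positive, and without cow A, D or G the IGF list had 1. This contrast shares all its arrays with the LH contrasts and with those between populations.

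**Figure D4:**
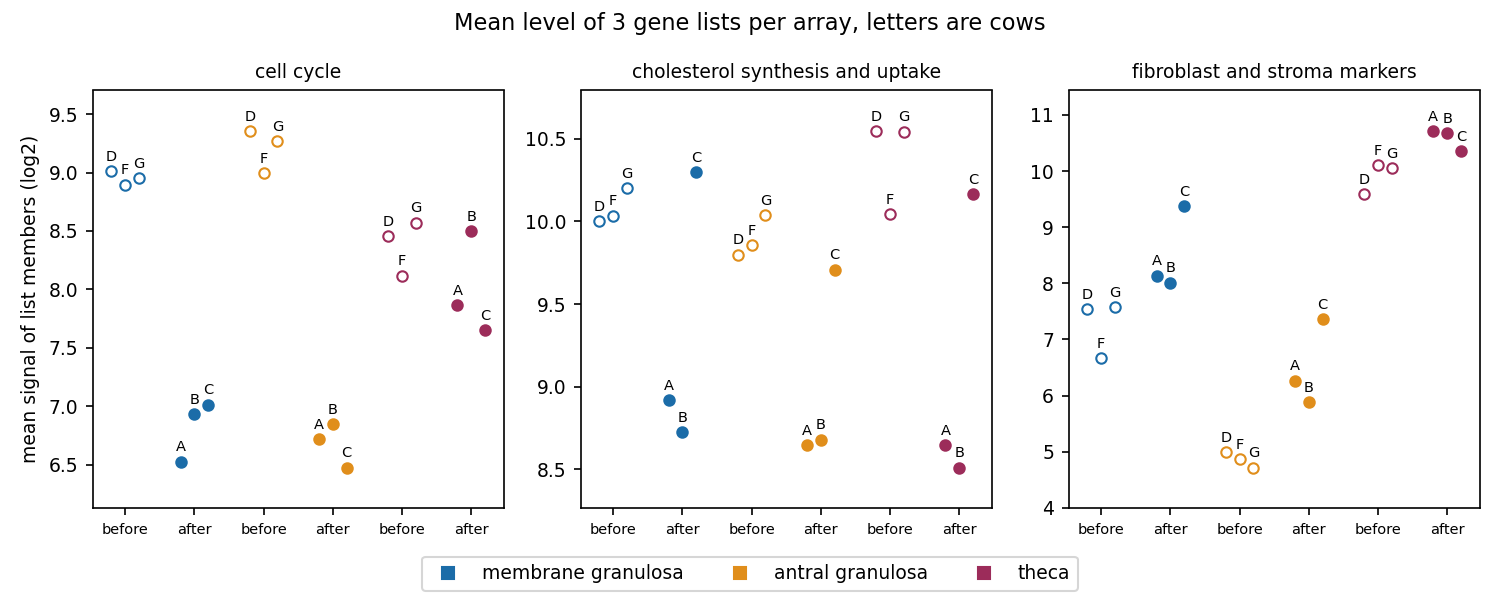
Mean log2 signal of the measured members of 3 gene lists on each array, by cell population (colour) and time (open before, filled after LH); letters are cows. Cow C lies above cows A and B in the cholesterol list in all 3 populations, its members by a median of 1.45, 0.84 and 1.42 in membrane granulosa, antral granulosa and theca.

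Before LH, CYP17A1 and STAR were higher in theca than in membrane granulosa, and FSHR and CYP19A1 lower. CYP17A1 was higher by 3.70 ± 0.66 (adjusted p = 0.000815) and STAR by 3.54 ± 0.80 (adjusted p = 0.00403). FSHR was lower by 3.32 ± 0.28 (adjusted p = 6.27e-06), and CYP19A1 was lower by 3.44 ± 0.61 (adjusted p = 0.000833). Calls numbered 8234, 3706 higher and 4528 lower, and at 2-fold or more 1867 and 1402. Of all probe sets 58.5% went the same way in all 3 cows, where chance gives 25%. The largest differences were those of the caveolar CAVIN2 (4.77 ± 0.51), ITGBL1 (4.72 ± 0.49), the ribonuclease BRB (4.70 ± 0.52), the lipocalin APOD (4.67 ± 0.60), the prostaglandin-degrading HPGD (4.67 ± 0.33) and the matrix protein ASPN (4.56 ± 0.36). The granin SCG2 (4.56 ± 0.74), the peptide receptor CALCRL (4.52 ± 0.42), the pericyte gene RGS5 (4.51 ± 0.65) and RARRES1 (4.47 ± 0.68) followed. Lower in theca were the ephrin EFNA5 (-3.57 ± 0.38), the nuclear receptor NR5A2 (-3.36 ± 0.62), CHST11 (-3.34 ± 0.32), NOS2 (-3.20 ± 0.40), GCLC (-3.19 ± 0.25), the cadherin CDH2 (-3.16 ± 0.39), the lactate transporter SLC16A3 (-3.13 ± 0.25) and the chaperone CLGN (-3.0 ± 0.37). The largest adjusted p among these 18 genes was 0.00103. Another probe set of SLC16A3 was not called (-0.36, adjusted p = 0.185), and one of NOS2 read -1.45 (adjusted p = 0.00062).

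ADAMTS1 (2.63 ± 0.22), PTX3 (by at least 1.78) and INSL3 (by 1.95 or more, adjusted p = 0.0119) were higher in theca before LH. INSL3 was the brightest probe set on the theca arrays of cows F and G, so its difference can be larger. TNFAIP6 (-2.74 ± 0.42), OXT (-1.62 ± 0.41), INHBA (-1.54 ± 0.33), HSD3B1 (-1.38 ± 0.30), LHCGR (-1.06 ± 0.32, adjusted p = 0.0231) and INHA (-0.80 ± 0.12) were lower. Another probe set of LHCGR was not called (-0.92, adjusted p = 0.169). Against antral granulosa LHCGR turned, at 0.44. Calls ended without 1 cow for STAR (F, adjusted p = 0.0639), INSL3 (F, adjusted p = 0.115), LHCGR (F or G, adjusted p = 0.158 and 0.106) and OXT (F or G, adjusted p = 0.0655 and 0.0508). VNN2 (0.45 ± 0.47) and CYP11A1 (-0.45 ± 0.50) were not called. PGR, called at adjusted p = 0.0328 and not without cow A, D or F, and PTGS2, called without cow C, lay below 4.62 in both populations, so neither is read.

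Fibroblast markers were higher in theca before LH in 15 of 15 (OGN (3.60 ± 0.39); 15 adjusted over the list alone), endothelial markers in 15 of 17 (PECAM1 (3.63 ± 0.33); 16 adjusted over the list alone) and smooth muscle markers in 9 of 11, with 2 lower (MYH11 (3.31 ± 0.28); 9 and 2 adjusted over the list alone). Extracellular matrix genes were higher in 22 of 29 and lower in 2 (COL5A2 (3.78 ± 0.40); 23 and 2 adjusted over the list alone). Leukocyte markers were higher in 10 of 22 and lower in 1 (11 and 1 adjusted over the list alone; 6 higher without cow G), inflammation genes in 12 of 28 (12 adjusted over the list alone) and theca markers in 7 of 11 with 1 lower (7 and 1 adjusted over the list alone). Camera called these 7 lists higher (adjusted p = 1.47e-06, 6.06e-09, 0.000275, 1.47e-06, 0.0131, 0.00286 and 0.00954). The lists had adjusted p = 0.285, 0.285, 0.338, 0.338, 0.579, 0.338 and 0.338 with an estimated correlation. Granulosa markers were lower in 10 of 13 (AMH (-2.77 ± 0.26); 11 lower and 1 higher adjusted over the list alone), and oestrogen-phase genes in 14 of 19 with 3 higher (14 and 3 adjusted over the list alone). Cell cycle genes were lower in 14 of 33 (15 adjusted over the list alone; 8 without cow D). Camera called these 3 lists lower (adjusted p = 1.07e-05, 0.000120 and 5.86e-05). They had adjusted p = 0.285, 0.285 and 0.539 with an estimated correlation. Steroidogenesis (7 higher and 5 lower), cholesterol (6 and 3), hormone receptors (3 and 7), the ovulatory cascade (9 and 5), proteases (11 and 5), angiogenesis (6 and 9) and BMP signalling (5 and 9) were not called as lists. Without cow G steroidogenesis had 4 higher. The IGF system (4 and 3), immediate early genes (4 and 1), Hedgehog signalling (0 and 0), red cell markers (1 and 0) and oocyte markers (2 and 0) were not called either.

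After LH, PECAM1 and UBE2C were higher in theca than in membrane granulosa, and PTGS2 and PTGES lower. PECAM1, an endothelial adhesion molecule, was higher by 3.62 ± 0.33 (adjusted p = 6.23e-05) and UBE2C, which drives mitotic exit, by 1.83 ± 0.19 (adjusted p = 8.79e-05). PTGS2 was lower by 2.59 ± 0.26 (adjusted p = 7.89e-05), and PTGES, which acts after it, was lower by 2.49 ± 0.31 (adjusted p = 0.000209). The largest differences were those of the water channel AQP1 (4.09 ± 0.54), CAVIN2 (4.04 ± 0.51), the endothelial EMCN (3.86 ± 0.47), the actin ACTA2 (3.79 ± 0.51), NFIB (3.78 ± 0.33), the collagen COL12A1 (3.74 ± 0.48), ADAMDEC1 (3.70 ± 0.48), the endothelin EDN1 (3.69 ± 0.37), ADGRF5 (3.64 ± 0.39) and LOXL4 (3.64 ± 0.45). Lower in theca were GRIA3 (-3.21 ± 0.33), the fatty acid carrier SLC27A2 (-2.97 ± 0.36), HS3ST5 (-2.73 ± 0.27), RBM24 (-2.73 ± 0.22), TOX (-2.67 ± 0.34), APOA2 (-2.58 ± 0.38), NR5A2 (-2.49 ± 0.62) and TNFRSF6B (-2.47 ± 0.24). The largest adjusted p of these 18 genes was that of NR5A2 (0.0104), a call that ended without cow A or B (adjusted p = 0.127 and 0.102). Calls numbered 6187, 2737 higher and 3450 lower, and at 2-fold or more 1367 and 917. Of all probe sets 57.3% went the same way in all 3 cows, where chance gives 25%. Without cow A the count was 2617 and without cow B 2467.

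FSHR (-1.97 ± 0.28), INHBA (-2.15 ± 0.33), INHA (-0.89 ± 0.12), OXT (-1.74 ± 0.41, adjusted p = 0.00820) and VNN2 (-1.38 ± 0.47, adjusted p = 0.0467) were lower in theca after LH. CYP11A1 (1.55 ± 0.50, adjusted p = 0.0393) and ADAMTS1 (0.70 ± 0.22, adjusted p = 0.0351; its other probe set 0.66, adjusted p = 0.0985) were higher, CYP11A1 not in every cow. Calls ended without 1 cow for OXT (A or B, adjusted p = 0.106 and 0.105), VNN2 (A, B, C or F, adjusted p 0.0604 to 0.353), ADAMTS1 (A, B or C, adjusted p 0.0626 to 0.276) and CYP11A1 (any cow but C, adjusted p 0.0634 to 0.203). STAR (2.22 ± 0.80, adjusted p = 0.0600), INSL3 (1.36 ± 0.53, adjusted p = 0.0786), TNFAIP6 (-1.19 ± 0.42, adjusted p = 0.0569), CYP17A1 (0.81 ± 0.66), HSD3B1 (-0.65 ± 0.30), CYP19A1, LHCGR, PTX3 and PGR were not called. Calls appeared without cow C for STAR (adjusted p = 0.00519) and HSD3B1 (0.0327), and without cow F for INSL3 (0.0122) and CYP17A1 (0.0382). TNFAIP6 was called without cow D or G (adjusted p = 0.0166 and 0.00281), and its other probe set with all cows (-1.93, adjusted p = 0.00643).

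Of 33 cell cycle genes 28 were higher in theca after LH (KIF20A (2.12 ± 0.26), BUB1B (1.84 ± 0.22); 28 adjusted over the list alone). Endothelial markers were higher in 14 of 17 (14 adjusted over the list alone), smooth muscle markers in 10 of 11 (MYH11 (3.01 ± 0.28); 10 adjusted over the list alone), fibroblast markers in 12 of 15 with 1 lower (OGN (3.00 ± 0.39); 14 and 1 adjusted over the list alone) and extracellular matrix genes in 20 of 29 with 2 lower (22 and 2 adjusted over the list alone). Camera called these 5 lists higher (adjusted p = 7.55e-14, 4.74e-10, 1.41e-07, 3.75e-06 and 7.67e-07). In turn, these had adjusted p = 0.283 for the first 4 and adjusted p = 0.299 for the matrix with an estimated correlation. Leukocyte markers were higher in 8 of 22 (12 adjusted over the list alone), inflammation genes in 10 of 28 with 1 lower (12 and 1 adjusted over the list alone), theca markers in 5 of 11 with 1 lower (7 and 1 adjusted over the list alone) and the IGF system in 4 of 13 with 1 lower (5 and 1 adjusted over the list alone). Camera called these lists higher too (adjusted p = 9.84e-05, 0.000596, 0.0196 and 0.0414). The lists had adjusted p = 0.310, 0.292, 0.318 and 0.310 with an estimated correlation. Granulosa markers were lower in 8 of 13 (8 adjusted over the list alone) and oestrogen-phase genes in 11 of 19 with 2 higher (11 and 2 adjusted over the list alone). Camera called both lower (adjusted p = 0.000596 and 0.00148), with adjusted p = 0.283 and 0.292 with an estimated correlation. Without cows A and B, each in turn, the leukocyte count was 0 and 1, the matrix count 12 and 11, and the inflammation count 5 each. Fibroblast markers then had 7 without cow B, granulosa markers 5 without cow B, theca markers 3 without cow B, and oestrogen-phase genes 7 and 6. Steroidogenesis (2 higher and 3 lower), cholesterol (1 and 5; 0 lower without cow A or B), hormone receptors (2 and 2), the ovulatory cascade (3 and 6), proteases (9 and 3), angiogenesis (5 and 7) and BMP signalling (7 and 8) were not called as lists. Hedgehog signalling (1 and 0), immediate early genes (0 and 4), red cell (1 and 0) and oocyte markers (1 and 0) were not called either. Without cows A and B, each in turn, proteases had 4 and 3 higher, angiogenesis 3 and 3 higher, BMP signalling 5 and 5 lower, and immediate early genes 1 and 1 lower.

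Before LH, 10 of 29 extracellular matrix genes were lower on antral than on membrane granulosa arrays. Camera called the list lower (adjusted p = 1.18e-16, and adjusted p = 0.137 with an estimated correlation). COL3A1, a fibrillar collagen, was lower by at least 6.14 (adjusted p = 0.000643), and COL1A2 was lower by 5.99 ± 0.54 (adjusted p = 0.000513). MGP, an inhibitor of calcification, was lower by at least 5.34 (adjusted p = 0.00134) on its brightest probe set, while another, above 4.62 on all these arrays, read -0.18 (adjusted p = 0.714). The basement membrane gene NID2 (-4.58 ± 0.50), the smooth muscle actin ACTA2 (by at least 4.07) and ADAMTS1 (-2.04 ± 0.22, adjusted p = 0.00108; its other probe set -0.02) were lower too. Higher on antral arrays were the defensins EBD (3.39 ± 0.70) and DEFB4A (3.39 ± 0.61), the calcium sensor GUCA1A (2.33 ± 0.43), the lipopolysaccharide co-receptor CD14 (by at least 1.64) and the cadherin CDH8 (by at least 0.59) (adjusted p 0.0211 to 0.0488). Other probe sets of CD14 (0.35, adjusted p = 0.588) and DEFB4A (2.70, adjusted p = 0.0815) were not called. These 5 calls ended without cow D (adjusted p 0.161 to 0.247) and without cow A (0.0524 to 0.0743). All but DEFB4A also ended without cow F (adjusted p 0.0637 to 0.105) and without cow B (0.0507 to 0.0973), and CD14 without cow G (0.116). Calls numbered 426, 165 higher and 261 lower, 231 and 221 after quantile normalization, and 11 and 92 with only the arrays compared. The count was 83 without cow D, 161 without cow A, 168 without cow B, 187 without cow G and 279 without cow F. In all 3 cows 37.6% of all probe sets went the same way, where chance gives 25%.

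The theca hormone INSL3 (-2.59 ± 0.53), STAR (-3.86 ± 0.80) and LHCGR (-1.50 ± 0.32) were lower on antral arrays before LH, at adjusted p of 0.0311, 0.0328 and 0.0385. Another probe set of LHCGR was not called (-1.33, adjusted p = 0.174). Calls ended without 1 cow for INSL3 (A, B, D or G, adjusted p 0.0612 to 0.191), STAR (A, D, F or G, adjusted p 0.0656 to 0.226) and LHCGR (any cow but D, adjusted p 0.0573 to 0.0879). CYP17A1 (-2.51 ± 0.66, adjusted p = 0.0717; 0.000527 without cow F), TNFAIP6 (-1.29 ± 0.42; adjusted p = 0.0353 without cow G), CYP19A1 (-1.01 ± 0.61), FSHR, CYP11A1, HSD3B1, INHA, INHBA, OXT, PGR, PTGS2, PTX3 and VNN2 were not called. The 10 matrix genes, FN1 (-3.07 ± 0.31) among them, were 19 adjusted over the list alone, 6 without cow G and 16 without cow C. Fibroblast markers were lower in 6 of 15 (OGN (by at least 3.82); 10 adjusted over the list alone), and smooth muscle markers in 3 of 11 (7 adjusted over the list alone; 1 without cow D or G). Proteases were lower in 7 of 29 and higher in 1 (PLAT (-1.66 ± 0.20); 9 and 1 adjusted over the list alone), with 4 lower without cow D or F, and the IGF system in 2 of 13 (3 adjusted over the list alone). Camera called the last 4 lists lower too (adjusted p = 1.61e-10, 1.54e-05, 3.45e-05 and 3.35e-05). They had adjusted p = 0.137, 0.254, 0.201 and 0.137 with an estimated correlation. BMP signalling was called lower as a list (adjusted p = 0.0195, and adjusted p = 0.20 with an estimated correlation) and cell cycle higher (median 0.26, adjusted p = 0.00108, and adjusted p = 0.610 with an estimated correlation). No member of either was called over all tests, and 0 and 2 were when adjusted over the list alone, with 5 and 7 at an unadjusted p under 0.05. Steroidogenesis (0 higher and 1 lower), cholesterol (0 and 1), hormone receptors (0 and 1), oestrogen-phase genes (0 and 1), the ovulatory cascade (1 and 4), angiogenesis (2 and 1) and immediate early genes (1 and 0) were not called as lists. Inflammation, Hedgehog signalling and markers of granulosa (0 and 1), theca (0 and 1), endothelium, leukocytes (1 and 0), red cells and the oocyte were not called either.

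After LH, 8 of 29 extracellular matrix genes were lower on antral than on membrane granulosa arrays, and none without cow A or B. Camera called the list lower (adjusted p = 5.51e-06, and adjusted p = 0.617 with an estimated correlation). ALDH1A1, which makes retinoic acid, was lower by 5.69 ± 0.69 (adjusted p = 0.00776). MGP was lower by 5.27 ± 0.75 (adjusted p = 0.0132) on its brightest probe set, while another, above 4.62 on all these arrays, read 0.26 (adjusted p = 0.464). COL3A1 was lower by 4.42 ± 0.68 (adjusted p = 0.0146). The lipocalin APOD (-4.09 ± 0.60), COL1A2 (-3.89 ± 0.54), the theca hormone INSL3 (-2.73 ± 0.53) and the cyclin CCND2 (-1.18 ± 0.21) were lower as well. Higher on antral arrays were the chemokine CCL3 (1.5 ± 0.22), the ubiquitin ligase NEURL1 (1.32 ± 0.25), the enolase ENO2 (0.98 ± 0.24), the carrier SLC25A29 (0.98 ± 0.18) and LRCH4 (0.95 ± 0.14) (adjusted p 0.0146 to 0.0459). Other probe sets of LRCH4 (0.67 and 0.35, adjusted p = 0.0580 and 0.146) were not called. Calls numbered 721, 343 higher and 378 lower, with 313 and 244 after quantile normalization, 363 and 333 with arrays centred, 605 and 404 with a random cow block, 368 and 858 with only the arrays compared, and 19 and 143 at 2-fold or more. Of all probe sets 49.8% went the same way in all 3 cows, where chance gives 25%. Without cow B, which leaves 2 cows after LH, no call was left, with 3662 probe sets at an unadjusted p under 0.05, and without cow A 5 were left. The count was 280 without cow C and 472 without cow D. Each of the 12 named genes lost its call without cow A (adjusted p 0.0688 to 0.248) and without cow B (0.0758 to 0.253). INSL3, CCND2, NEURL1, SLC25A29 and ENO2 also lost it without cow C (adjusted p 0.0504 to 0.157), and ENO2 without any 1 of the 6 cows. STAR (-1.75 ± 0.80), CYP11A1 (-0.83 ± 0.50), CYP19A1, CYP17A1, HSD3B1, LHCGR, FSHR, ADAMTS1, PTX3, PTGS2, VNN2, TNFAIP6, OXT, INHBA, INHA and PGR were not called. The other probe set of ADAMTS1 was (-1.23, adjusted p = 0.0378).

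Fibroblast markers were lower on antral arrays after LH in 6 of 15 (10 adjusted over the list alone), matrix genes in 8 of 29 (14 adjusted over the list alone) and proteases in 4 of 29 (5 adjusted over the list alone). Camera called these 3 lists lower (adjusted p = 1.45e-07, 5.51e-06 and 0.0289), each with adjusted p = 0.617 with an estimated correlation. Without cow A these counts were 1, 0 and 0, and without cow B 0 each. Without cow C 4 matrix genes and 2 proteases were lower. Cholesterol genes were called lower as a list (median -0.32) and oocyte markers higher (median 0.53), both at adjusted p = 0.0410 and at adjusted p = 0.617 with an estimated correlation. No member of either was called over all tests, and 0 and 1 were when adjusted over the list alone, with 5 and 4 at an unadjusted p under 0.05. The 17 other lists were not called, with 3 of 11 smooth muscle markers, 2 of 33 cell cycle genes and 1 of 11 theca markers lower, and at most 1 member higher or lower in each of the others.

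For the difference in LH effect between antral and membrane granulosa, limma called 0 probe sets, with 2236 at an unadjusted p under 0.05. The differences of the 2 times did not overlap for 15.5% of probe sets, where chance gives 10%. NID2, a basement membrane protein, had the smallest adjusted p of the named genes (4.05 ± 0.71, adjusted p = 0.198). ADAMTS1 (1.74 ± 0.31, adjusted p = 0.206; its other probe set -1.20), FN1 (2.35 ± 0.44) and CCND2 (-1.59 ± 0.30), both at adjusted p = 0.236, followed. Calls numbered 20 without cow G and 6 without cow F. NID2 (adjusted p = 0.000299), ADAMTS1 (0.0331) and CYP17A1 (2.99 ± 0.93; 0.00340) were called without cow F. Camera called extracellular matrix genes more positive (median 0.37) and cell cycle genes more negative (median -0.40), both at adjusted p = 9.94e-05 and at adjusted p = 0.760 with an estimated correlation. No member of either was called over all tests, and 2 matrix genes and 0 cell cycle genes were when adjusted over the list alone. At an unadjusted p under 0.05 were 6 and 10. The 20 other lists and the other genes fixed for naming, among them PTX3, PTGS2, CYP19A1, VNN2 (-0.28 ± 0.66), LHCGR (1.12 ± 0.46) and STAR (2.11 ± 1.13), were not called. The arrays are those of the LH contrasts in both populations.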

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

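The tests on cells of another type, on dilution, on cow C and on RNA degradation were chosen after the result was seen; the tests of a difference between populations and the regroupings of the cows were planned.

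The LH effect differed between theca and membrane granulosa for 2192 probe sets, by limma's test of the difference itself. Among named genes the most positive were SRGN (3.50), RASGEF1B (3.41), SLC7A5 (3.40), CCND2 (3.34) and DLL4 (3.34), and the most negative CAV1 (-5.40), CLDN11 (-5.17, and -2.28 by another probe set), LMO7 (-4.96), TGFB2 (-4.96) and P4HA3 (-4.53). By camera the lists that differed were cell cycle (median 1.87), granulosa markers (0.83), cholesterol synthesis and uptake (-0.59), immediate early and heat shock genes (-0.48) and the ovulatory cascade (-0.21). Between antral and membrane granulosa, extracellular matrix (0.37) and cell cycle (-0.40) differed. None of these 7 list calls held with an estimated correlation.

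Groups of 3 make 10 splits of the arrays, too few for a share under 0.05. In each contrast but the last, 1 split, the real one, gave a count as large. In the other splits a real difference falls within the groups and widens their spread. Their low counts therefore do not measure what chance alone would call. The LH effect gave 5041 calls in membrane granulosa, 5391 in antral granulosa and 941 in theca, against at most 1, 2 and 11 in another split. Theca minus membrane granulosa gave 8234 before and 6187 after LH, against at most 3 and 0, and 0 in the splits that part all pairs of a cow. Antral minus membrane granulosa gave 426 before and 721 after LH, against at most 7 (parting all pairs) and 0. The difference in LH effect gave 2192 calls for theca, against 0. For antral granulosa it gave 0, as did all 10 splits, with 2236 probe sets at an unadjusted p under 0.05 in limma.

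Probe sets lower on antral than on membrane granulosa arrays numbered 261 before and 378 after LH, with COL3A1 among them (means of 10.8, 3.91 and 13.5 on membrane, antral and theca arrays before LH), and 55.6% and 56.3% of them lay higher on theca than on membrane granulosa arrays. For the 85 before and 62 after LH called lower on theca too, the test on theca and stroma cells on the membrane granulosa arrays does not decide. Their RNA would put the membrane level between the antral and the theca level. Of the 62 chosen after LH, 29 (46.8%) lay highest on the membrane array in all 3 cows before LH, and of the 85 chosen before LH, 41 (48.2%) in all 3 cows after LH, against 8.02% and 6.69% of all probe sets. Their 95% exact binomial intervals (34.0% to 59.9% and 37.3% to 59.3%) lie above the shares of all probe sets. This argues against such cells as the source for the probe sets that lay highest there. For the others they cannot be told apart, as the shares stay below the majority that was set as the bound. For the 118 and 135 called higher on theca, such cells may be a source: of theca-rich probe sets chosen in the other 3 cows, 136 of 143 (95.1%) before and 223 of 233 (95.7%) after LH were higher on membrane than on antral arrays, against 43.8% and 42.7% of all. The median share of theca RNA would be 9.70% (quartiles 6.04 to 15.7) before and 15.1% (10.7 to 20.9) after LH, over 107 and 103 theca-rich probe sets. These were chosen as lower on antral than on membrane arrays in the same cows, which can overstate the share. At the upper quartile before LH it dilutes granulosa transcripts by 0.25, a loss that can be overstated too. Probe sets called higher on antral arrays without cow D, F or G rose in that cow by medians of 0.38, 0.37 and 0.21, with lower quartiles of 0.26, 0.12 and -0.13 around that loss, so dilution cannot be told apart for them. These tests, and those on degradation, replaced earlier forms that did not decide, or whose outcome the choice of probe sets had fixed. Real differences between the granulosa layers stay open, untested.

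Cow C stood apart from cows A and B after LH, with the cholesterol list higher by a median of 1.45 in membrane granulosa, 0.84 in antral granulosa and 1.42 in theca, OXT at 14.4 against 9.89 and 9.33 in theca, and CYP11A1 at 13.1 against 8.64 and 8.04 in membrane granulosa. More theca cells on its membrane granulosa array cannot act on its theca array, where the cholesterol list was higher too (1.42). So they do not account for the rise there. For the membrane array this does not decide, since theca RNA of cow C would itself bring high levels of this list. That array correlated with the theca array of the same cow at 0.983, against 0.946 in cow A and 0.946 in cow B. For fibroblast markers they may be a source, since these were higher on its membrane and antral granulosa arrays (1.35, and 0.82 with 12 of 15 above 0) and not on its theca array (-0.25). RNA degradation would raise the 3' minus 5' difference of control transcripts. On the theca array of cow C that difference was the lowest of the 6 theca arrays for all 3 controls (actin 1.14 against 1.51 to 1.91, GAPD 0.275 against 0.285 to 0.447, EF1A -2.30 against -1.80 to -1.42), and for 2 of them, actin and EF1A, by more than the standard deviation of the others. This argues against degradation of cow C's RNA for the rise of the cholesterol list on that array. It does not test whether less intact RNA in cows A and B lowered the list on their theca arrays. On its granulosa arrays the difference was higher than in cows A and B for 1 control, EF1A, and lower for 1, GAPD, and actin was lower on the membrane (1.336 against 1.352 and 1.356) and between them on the antral array, so there degradation cannot be told apart. A difference in the time or stage of this follicle's response stays open, and no biological explanation was tested.

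Among the 510 probe sets lower in theca after LH, 219 were called higher and 142 lower on theca than on membrane granulosa before LH. Of the falls called higher on theca without cow D, F or G, 95.7%, 93.9% and 98.5% lay above both granulosa arrays on the theca array of that cow, with medians of 1.13, 1.14 and 1.27 above the higher one. A loss of granulosa cells from the theca arrays would not lower such probe sets, and is argued against for that part. For the 142, CYP19A1 among them (13.7 on membrane granulosa and 10.3 on theca before LH), such cells could be a source. The theca level less the membrane granulosa level was lower in cow G than in cows D and F by a median of -0.77 for granulosa markers and -0.15 for these 142 (quartiles -0.61 to 0.09), which does not decide. A fall within theca cells stays open, untested.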

How the results depend on the processing

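Antral granulosa in place of membrane granulosa was chosen after seeing the data; all other alternatives were planned, and all gave a value. Where no cause is named, the cause was not tested.

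Counts past the threshold moved by over 1.5 times under these settings. With 1 probe set per gene, which tests fewer probe sets, they were 2497, 2742 and 524 for LH in membrane granulosa, antral granulosa and theca, 3823 and 3053 for theca minus membrane granulosa before and after LH, 339 for antral minus membrane granulosa after LH, and 1184 for the difference in LH effect of theca. With a 2-fold minimum, stricter by construction, they were 2588, 2720 and 569, then 3269 and 2284, and 175 and 162 for antral minus membrane granulosa before and after LH. With only the arrays compared they were 514 for LH in theca, 103 before and 1226 after LH for antral minus membrane granulosa. For the difference in LH effect of antral granulosa the count of 0 became 1 with quantile normalization, without the dimmest probe sets, with 1 probe set per gene and with trend and robust, and 3 with only the arrays compared and with a random cow block.

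Without the cow as a block, the within-cow counts fell to 134 and 297 for antral minus membrane granulosa before and after LH and 1016 for the difference in LH effect of theca. With the replicate number as a block the LH counts were 5524, 5832 and 1204, and with the cow as a random block (consensus correlation 0.20) 5230, 5514 and 1042, within 1.5 times. Among named genes, 19 calls were lost without the cow block, and 9 were lost and 3 gained with a random one.

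With a cow left out, counts ranged from 3387 to 5405, 3932 to 5791 and 439 to 1016 for LH in membrane granulosa, antral granulosa and theca. For theca minus membrane granulosa they were 5993 to 8367 before and 2467 to 6255 after LH, and for antral minus membrane granulosa 83 to 478 and 0 to 600. For the differences in LH effect they were 1074 to 2192 and 0 to 20. The overlaps ranged from 2670 to 3923, 289 to 714 and 282 to 686. Named genes lost a call in 113 of such fits and gained one in 27, with no change of direction.

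Quantile normalization moved no value by over 0.21 and centring no array by over 0.07. Of 198 list medians 12 changed sign, all within 0.07 of 0. Directions of called genes turned for LHCGR with antral granulosa in place (0.44 before LH) and for other probe sets of CYP19A1 (0.069, LH in theca), MGP (0.15 and 0.30 before, 0.26 after LH) and LHCGR (0.053, antral minus membrane granulosa before LH). All of these other probe sets but that of MGP after LH lay below 4.62 on all arrays of a group compared, where a sign says little, and 48 other probe sets had no call where the gene's brightest had. Another 5 had a call where the brightest had none, in the same direction. Of genes not called, 16 other probe sets had the other sign, also not called, such as ADAMTS1 (-1.20) in the difference in LH effect of antral granulosa. With an estimated correlation 68 list calls were lost and 130 of 198 lists were unchanged. Fry lost 13 and gained 17, and leaving out a cow lost 33 and gained 43 list calls. Signal over background limits the 8005 dimmest probe sets, with means below 4.62, where a change can be missed.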

Other observations

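The genes and tests in this part were chosen after their values were seen. Some genes had an LH call in theca and none in either granulosa population, with a called difference from membrane granulosa. They numbered 98 probe sets, 28 higher and 70 lower, for 50 genes. Both calls held with each cow left out in turn for 12 genes, all lower. They were SLC1A3, a glutamate transporter (-3.40, adjusted p = 4.86e-05), OIT3 (-2.31), the guanylate-binding protein GBP4 (-1.88), SMIM10 (-1.61), RANGRF (-0.94) and the mitochondrial factor MRRF (-0.94), and others below 4.62 on all theca arrays after LH. These were the chemokine CXCL14 (by at least 2.52), PEBP4 (by at least 1.21), the potassium channel subunit KCNMB1 (by at least 1.09), the phosphatase subunit PPP2R2B (by at least 0.86), the lipid droplet protein PLIN5 (by at least 0.84) and BBOX1 of carnitine synthesis (by at least 0.55). Of the 12, 7 lay below 4.62 on all granulosa arrays before LH, where a fall cannot be seen, and only RANGRF and MRRF lay above it on all of them. So for most of these genes the lack of a granulosa call does not show a response of theca alone. The highest adjusted p among the 12 genes without 1 cow was 0.0231 in theca and 0.0391 for the difference. Rises such as those of the coagulation factor F5 (by at least 1.1) and the carbonic anhydrase CA4 (1.92) did not hold both calls with every cow left out.

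Some genes were called in opposite directions in theca and granulosa. SLC7A5 rose in theca (2.95) and fell in antral granulosa (-0.96), and TM7SF2, a sterol reductase, fell in theca (-2.24) and rose in antral granulosa (1.01). SIPA1, a GTPase activator, fell in theca (-0.94) and rose in membrane granulosa (0.75), and the giant muscle protein NEB was called lower in theca and higher in antral granulosa, with a mean below 4.62 in antral granulosa at both times, so no size is given. For these 4 genes the theca call and the called difference from membrane granulosa held with each cow left out. PDIA5, TCF7, NOL3, DDIT4, UCHL3, PEBP1, TSKU and HSD17B10 were also called in opposite directions, and lost at least 1 of both calls when some cow was left out. The opposite granulosa calls of SLC7A5 and TM7SF2 had adjusted p of 0.0263 and 0.0484.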
